A study of Chlamydomonas reinhardtii with 18 samples.

How the data were processed

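The labels describe total RNA from Chlamydomonas reinhardtii WT (CC-4532) and tpt10b cells at 0 h in light and after 24 h and 48 h of darkness. DNase-treated RNA was primed with random hexamers, and the libraries were paired-end. Groups and replicate numbers were taken from the sample titles, which number replicates 1 to 3; the descriptions of the tpt10b 48 h samples number them 4 to 6. Should that mark another batch, it would coincide with tpt10b at 48 h and affect each comparison that uses that group. The processing notes name HISAT2 2.0.5 and StringTie 1.3.3b without saying what each was used for, and a legend names the CC-4532 v6.1 annotation. The deposited table holds TPM values computed by the authors for 17693 genes in 18 libraries, 4408 of them with a symbol, and each column adds to 1e+06. Neither the counting tool, the strandedness nor a poly(A) selection is stated, and the files give no gene coordinates. Should a poly(A) selection have been used, organelle-encoded values would also reflect how far organelle RNA was captured.

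TPM multiplied by the length given for each gene, and scaled by 1 factor per library, came within 0.01 of whole reads for 100% of genes, with 59603478 to 87965038 reads per library. Lengths were multiples of 3 for 94.4% of genes and are called coding length. Genes with a TPM of at least 1 in at least 3 of the 18 libraries were kept, 14731 genes, 4120 with a symbol. In data simulated from these libraries, 200 genes, as many up as down, were made 1.5-, 2- or 4-fold different at 24 h. The test recovered 37.9%, 80.3% and 100% of them and made 9 false calls among 13955 unchanged genes. Genes were drawn independently, with the same spread in every group. The simulation therefore does not cover a one-sided shift of many genes or groups of unequal spread.

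Values were log2(TPM + 1), fitted with limma 3.58.1 in R 4.3.3 with 1 mean per group and an empirical Bayes variance trend. There were 11 contrasts: tpt10b against WT at each of 3 times, 24 h and 48 h against 0 h and 48 h against 24 h in each genotype, and the interaction of genotype with each dark time. P-values were adjusted by Benjamini and Hochberg within each contrast, with a threshold of 0.05. Measures with 1 value per library were compared with an exact two-sided permutation test, for which 3 against 3 libraries cannot go under 0.1. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, for lists of at least 5 measured members, adjusted over the 32 lists tested in each contrast. Of 30 lists fixed from background knowledge, 1 matched no symbol, and 5 lists were added after the symbols, but not the values, had been read. The groups, contrasts, main test, 30 lists, the locus assigned to CreTPT10 and the rule for named genes were fixed before the data were examined. The plan had said that the targeted gene would be identified from the files or the reference alone, and since neither names it, its use here departs from that plan.

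Genes were named by a rule. The targeted locus and its family came with the 10 largest rises and 10 largest falls of each genotype comparison and of each dark time against 0 h, and with the 5 largest each way of each interaction. These had passed the threshold, had a mean of at least 5 TPM in the higher group, and carried a symbol, as no descriptions were given. No overlap between groups was a further condition, except for the interactions. Up to 4 members of each list with the smallest adjusted p, and every member of lists under 8, were added. Some genes that met the rule are not reported here. Plastid loci given by identifier met the rule but carry a symbol that is not unique among the genes. FEA2 and the loci without a symbol, given by identifier, were chosen after their values were seen.

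The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at a mean of 5 TPM, median-of-ratios rescaling, quantile normalisation, a replicate block, a robust variance prior, a fit on the compared groups only, and each replicate left out. After the data were seen, 6 more were added: limma-voom on the recovered reads, TPM without ribosomal protein and organelle genes, library weights, corrected symbol matching of the lists, the list tests without WT 48 h replicate 2, and the numbers of list members with each library left out. Replicate numbers were not used as pairs in the main test: of 45 correlations between deviations of libraries with the same number, 6 were above 0.1, and 0 of 18 libraries correlated best with their own number. Data handling used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. No library was left out of the main test.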

Results

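RNA was sequenced from the green alga Chlamydomonas reinhardtii in 6 groups of 3 biological replicates, 18 libraries in all. The wild type (WT) was strain CC-4532, and tpt10b was a knockout of CreTPT10, a gene of the triose phosphate translocator family whose members exchange phosphorylated sugars across membranes. Cells grew on TAP, a medium that contains acetate, in low light of about 30 µmol photons per square metre per second to mid-log phase. Samples taken then are called 0 h, and further samples followed 24 h and 48 h of darkness. The deposited values, TPM, are transcript abundances corrected for length and scaled to a fixed total, here for 17693 genes. Multiplied by coding length they gave whole reads, 59603478 to 87965038 per library. Changes are log2 ratios of TPM + 1 with the standard error of the fitted model, and levels are mean TPM with SD, n = 3 libraries per group. The largest changes are named among genes with a symbol and a mean of at least 5 TPM in the higher group. In every gene named as a largest change between groups, all 3 libraries of 1 group lay above all 3 of the other, which chance gives for 10% of genes. The adjusted p-values measure the spread between samples only, and nothing in the labels says whether replicates came from separately grown cultures. A value given with libraries left out is the range over the libraries of the groups compared, each left out in turn. For the members of a list it is given where the larger of the numbers in each direction, or a number that reaches 4, moves by over 1.5 times, and smaller numbers can move as well.

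The libraries differed in composition as well as in single genes. Cytosolic ribosomal protein transcripts made up a mean of 32.2% of TPM in WT and 27.1% in tpt10b at 0 h, 36.3% and 40.2% at 24 h, and 38.3% and 33.7% at 48 h. Light-harvesting antenna transcripts fell from 5.32% of TPM at 0 h to 1.02% at 24 h and 0.911% at 48 h in WT, with 5.46%, 0.840% and 1.24% in tpt10b. Genes with reads numbered 15764 on average in tpt10b at 24 h against 16636 in WT, a difference of -872 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow). Correlations of log2 TPM across genes, which are not independent replicates, ran from 0.975 to 0.981 between the tpt10b 24 h libraries. WT 48 h replicate 2 correlated at 0.963 and 0.970 with the other WT 48 h libraries, which correlated at 0.991 with each other. Because TPM adds to a fixed total, each result was also computed after median-of-ratios rescaling, called rescaling here. It moved the median log2 difference of all genes between tpt10b and WT from 0.41 to -0.02 at 0 h, from -0.23 to 0.03 at 24 h and from 0.12 to 0.01 at 48 h. In darkness against 0 h it moved the median from 0.21 to 0.01 at 24 h in WT, and from -0.53 to -0.06 at 24 h and -0.20 to 0.03 at 48 h in tpt10b.

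**Figure D1:**
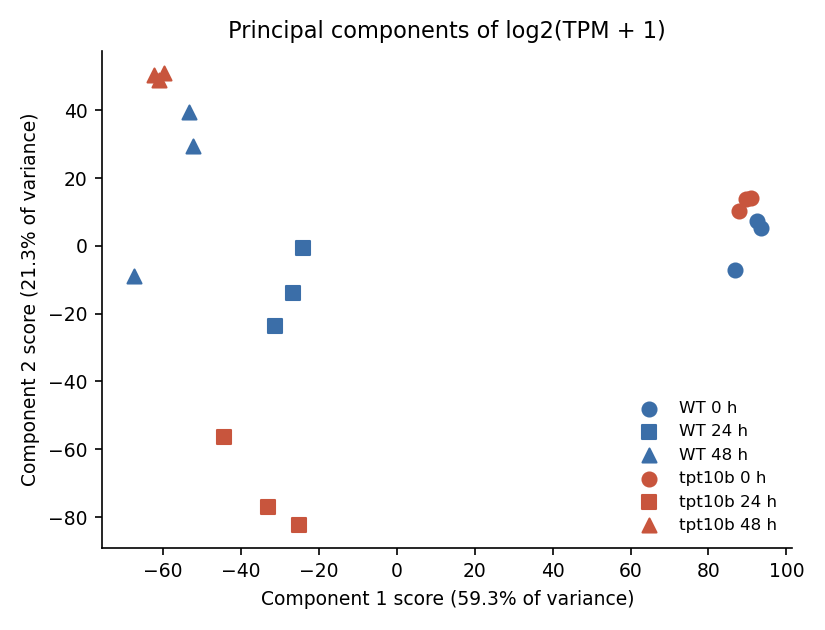
Principal components of log2(TPM + 1) for the 18 libraries, 1 point per library. The axes are the component that holds 59.3% of the variance and the component that holds 21.3%. On the latter the 3 tpt10b 24 h libraries lie at the negative end, below every other library.

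The targeted transcript was low in tpt10b at every time. The locus Cre08.g379350 averaged 7.50 ± 0.839 TPM in tpt10b and 58.3 ± 3.53 in WT at 0 h, 1.87 ± 0.931 and 38.3 ± 5.57 at 24 h, and 6.20 ± 0.524 and 64.2 ± 19.4 at 48 h. This left 12.9%, 4.88% and 9.66% of the WT level. The log2 differences were -2.81 ± 0.21 (adjusted p = 1.19e-07), -3.81 ± 0.21 (adjusted p = 6.97e-09) and -3.14 ± 0.21 (adjusted p = 7.86e-08), with each tpt10b library below each WT library. In WT the transcript changed by -0.60 after 24 h of darkness (adjusted p = 0.0162, call lost without WT 0 h replicate 1 or WT 24 h replicate 2), and its change at 48 h was 0.10 (adjusted p = 0.685). Reads from the locus remained, between 162 and 923 per tpt10b library. The files give no symbol for this locus, and its assignment to CreTPT10 rests on background knowledge. Of the related translocators with symbols, TPT3 was 0.61 ± 0.11 higher in tpt10b at 0 h (adjusted p = 1.77e-04, and 0.06 with no call after rescaling) and 0.38 ± 0.11 higher at 24 h (adjusted p = 0.00947, call lost without WT 24 h replicate 2), with 0.21 at 48 h (adjusted p = 0.218), while TPT2 differed by 0.24, -0.04 and -0.24 at the 3 times without passing the test.

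**Figure D2:**
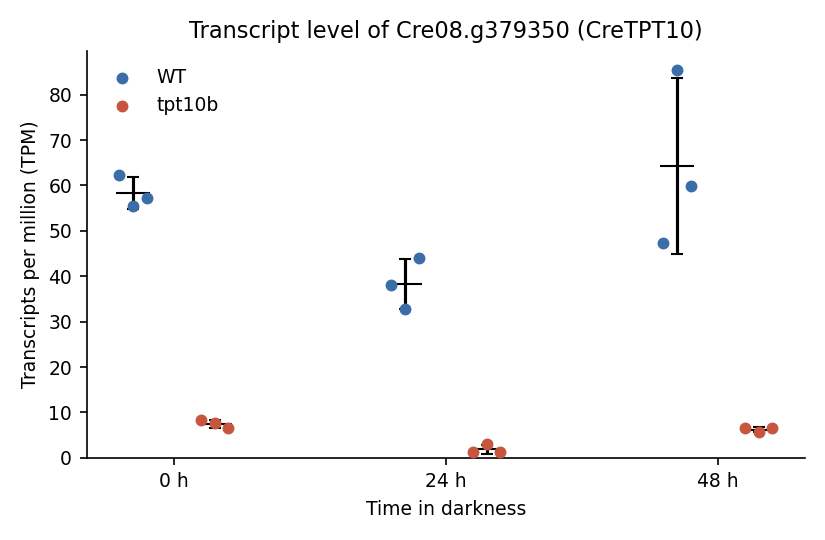
TPM of Cre08.g379350, assigned to CreTPT10, in each library at 0 h in light and 24 h and 48 h in darkness, with the mean and SD of each group of 3. At each time the 3 tpt10b libraries sit below the 3 WT libraries.

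At 0 h, before darkness, 15 of 15 fermentation genes were higher in tpt10b and 39 of 45 flagellar genes were lower. PFR1 (Cre02.g095137), pyruvate:ferredoxin oxidoreductase, stood at 21.9 ± 1.35 TPM in tpt10b and 1.49 ± 0.386 in WT, a log2 difference of 3.21 ± 0.21 (adjusted p = 3.35e-08). The ferredoxin gene FDX5 (Cre17.g700950) reached 239 ± 35.0 TPM against 40.5 ± 12.9 (2.57 ± 0.34), and PFH10 (Cre02.g084450), a prolyl 4-hydroxylase, 489 ± 39.96 against 85.9 ± 18.1 (2.51 ± 0.17). The flagellar associated protein gene FAP126 (Cre12.g536100) stood at 238 ± 30.3 TPM in tpt10b and 931 ± 246 in WT (-1.93 ± 0.32). The comparison asks what loss of the transporter changes in growing, lit cells.

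The other largest rises at 0 h were HCP1 (2.36), a hybrid cluster protein, CGL95 (2.33), FAP338 (1.99) and the sodium and phosphate symporter PTB2 (1.85). They also included the Pumilio-family genes PUF4 (1.83) and PUF1 (1.82), and nad2 (1.74), a mitochondrial complex I subunit. The largest falls were the plastid loci CreCp.g802284 (-2.91) and CreCp.g802322 (-2.89), and chlL (-2.20), a subunit of the light-independent protochlorophyllide reductase. Both plastid loci carry symbols that are not unique, and with values so near each other they may not be separate signals. The nucleoredoxin NRX3 (-2.10), FAP17 (-1.99), FBB5 (-1.95), FAP108 (-1.89), FAP149 (-1.82) and FAP141 (-1.81) followed. All of these, with PFR1, FDX5, PFH10 and FAP126, kept their direction and their call after rescaling.

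Of 15 fermentation genes, 15 were higher and 0 lower (15 and 0 adjusted over the list alone, 10 and 0 after rescaling). Among them were ADH1 (1.54) and HCP2 (1.48). The fermentation list gave adjusted p = 1.36e-04, and adjusted p = 0.739 with an estimated correlation. Of 18 starch synthesis genes, 17 were higher and 0 lower (17 and 0 adjusted over the list alone, 8 and 1 after rescaling). The ADP-glucose pyrophosphorylase gene AGP2 was at 1.10, PGI1 at 0.95 and the soluble starch synthase SSS3A at 0.99. The starch synthesis list gave adjusted p = 0.00417, and adjusted p = 0.871 with an estimated correlation. Of 45 flagellar genes, 0 were higher and 39 lower (0 and 40 adjusted over the list alone, 0 and 45 after rescaling). They included the radial spoke gene RSP9 (-1.43) and the intraflagellar transport genes IFT20 (-1.34), IFT54 (-1.17) and IFT74 (-1.13). The flagellar list gave adjusted p = 1.80e-34, and adjusted p = 0.133 with an estimated correlation.

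Of 73 cytosolic ribosomal protein genes, 1 was higher and 21 lower (0 and 11 adjusted over the list alone, 0 and 65 after rescaling, 11 to 19 lower with libraries left out). RPL9 was at -0.57 and RPL32 at -0.62. The cytosolic ribosome list gave adjusted p = 9.89e-13, and adjusted p = 0.133 with an estimated correlation, and the share of TPM held by these genes, given above, was lower too. Of 20 proteasome genes, 18 were higher and 0 lower (2 and 0 after rescaling), in a list added after the symbols were seen. The proteasome list gave adjusted p = 0.00481, and adjusted p = 0.871 with an estimated correlation. Of 21 antenna genes, 1 was higher and 0 lower (0 and 0 adjusted over the list alone, 0 and 15 after rescaling). Their median was 0.02 (-0.02 to 0.09 with libraries left out), their mean 0.05 and their median after rescaling -0.54. They ranked low against all genes. The antenna list gave adjusted p = 0.0325, and adjusted p = 0.871 with an estimated correlation. Of 51 cell cycle genes, 12 were higher and 5 lower (10 and 3 adjusted over the list alone, 1 and 26 after rescaling, 2 to 15 lower with libraries left out). Here the median was -0.01 (-0.17 to 0.09 with libraries left out) and the mean 0.06, and the list test pointed down. The cell cycle list gave adjusted p = 0.00417, and adjusted p = 0.871 with an estimated correlation. Of 10 photosystem I genes, 0 were higher and 1 lower (0 and 8 after rescaling), another added list, with PSAK1 at -0.38. The photosystem I list gave adjusted p = 0.0483, and adjusted p = 0.787 with an estimated correlation.

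Single genes of lists whose test did not pass at 0 h included the acetate kinase ACK1 (1.55) and the carbonic anhydrases CAH2 (1.58) and CAH4 (1.13), all higher. The zeaxanthin epoxidase ZEP1 (1.25) and ELIP5 (1.63) were higher as well. LCI9 (-1.15), the alternative oxidase AOX1 (-1.09) and NSG1 (-1.57) were lower.

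In limma at an adjusted p under 0.05, 8831 of 14731 genes differed between tpt10b and WT at 0 h, 7477 higher and 1354 lower in tpt10b, and 9 of 32 lists passed. After rescaling 5057 genes differed and 38.5% of them were higher, where 84.7% were higher in TPM as deposited. Filtering at a mean of 5 TPM left 5297 genes, quantile normalisation 5456 and voom weights on the recovered reads 5139.

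After 24 h of darkness most genes that differed were lower in tpt10b in TPM as deposited, with 14.2% higher, against 48.0% higher after rescaling. ACS3 (Cre07.g353450), an acetyl-CoA synthetase, stood at 25.1 ± 7.15 TPM in tpt10b and 225 ± 70.7 in WT, a log2 difference of -3.11 ± 0.40 (adjusted p = 4.65e-05). NDA3 (Cre05.g232200), a type II NADH dehydrogenase, was -2.71 ± 0.34 and AMB2 (Cre06.g270350), a beta-amylase, -2.67 ± 0.39. PTB2 (Cre07.g325741) was the largest rise among genes with symbols, 47.7 ± 17.6 TPM in tpt10b and 9.74 ± 0.988 in WT (2.11 ± 0.23), and most of the other largest rises were plastid-encoded. The comparison asks how the mutant and WT differ when acetate and stored carbon are the carbon sources. The tpt10b 24 h libraries stand apart in genes with reads and in their correlations, as given above, and every value in this comparison rests on them.

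The remaining largest falls at 24 h were PRR1 (-3.05), CYCAB1 (-2.69), the malate dehydrogenase MDH5 (-2.69), CPL2 (-2.66), the putative acetate transporter GFY3 (-2.57), the protein kinase SNRK2H (-2.56) and the sulfiredoxin SRX1 (-2.49). The galactolipid lipase gene PGD1 was -2.25 ± 0.15. Rises included petL (1.63) of the cytochrome b6f complex, psbT (1.49), psbN (1.14, call lost without WT 24 h replicate 2 or tpt10b 24 h replicate 1) and ycf12 (1.36) of photosystem II, the plastid ribosomal genes rps12 (1.51) and rpl20 (1.44), and RRP7 (1.37).

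Of 73 cytosolic ribosomal protein genes, 22 were higher and 8 lower (23 and 9 adjusted over the list alone, 39 and 1 after rescaling, 11 to 27 higher with libraries left out, 4 to 11 lower with libraries left out). RPL40 was at 0.49 and RPS27E2 at -1.82, and the list ranked high. The cytosolic ribosome list gave adjusted p = 3.26e-07, and adjusted p = 0.564 with an estimated correlation. Of 64 nuclear respiratory chain genes, 18 were higher and 18 lower (23 and 20 adjusted over the list alone, 33 and 8 after rescaling, 8 higher without WT 24 h replicate 2). Their median was 0.00 (-0.06 to 0.02 with libraries left out) and their mean -0.11, yet the test against all genes pointed up. The respiratory chain list gave adjusted p = 0.00368, and adjusted p = 0.975 with an estimated correlation. Of 18 histone genes, 1 was higher and 0 lower (1 and 0 adjusted over the list alone, 3 and 0 after rescaling, 2 higher without tpt10b 24 h replicate 2). HFO26 was at 1.06, and the test pointed up. The histone list gave adjusted p = 0.00646, and adjusted p = 0.326 with an estimated correlation, and adjusted p = 0.315 after rescaling.

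Several other lists had lower members at 24 h, but their list test did not pass against the shifted background of all genes. Of 17 acetate and glyoxylate genes, 1 was higher and 10 lower (1 and 10 adjusted over the list alone, 3 and 6 after rescaling). They included GFY1 (-1.36) and GFY4 (-1.99), at a list adjusted p = 0.333. Of 16 autophagy genes, 0 were higher and 10 lower (0 and 10 adjusted over the list alone, 3 and 7 after rescaling). ATG1 was at -1.57 and ATG8 at -1.23, at a list adjusted p = 0.217. Of 29 chaperone genes, 1 was higher and 18 lower (1 and 20 adjusted over the list alone, 3 and 6 after rescaling, 11 lower without WT 24 h replicate 2). BIP2 was at -1.41 and HSP70A at -1.26, at a list adjusted p = 0.217. Of 18 carbon-concentrating genes, 1 was higher and 11 lower (2 and 11 adjusted over the list alone, 4 and 7 after rescaling). CAH8 was at -2.19 and CCM1, a regulator of that mechanism, at -2.01, at a list adjusted p = 0.412. Of 16 starch breakdown genes, 0 were higher and 9 lower (0 and 9 adjusted over the list alone, 3 and 6 after rescaling). The alpha-amylase AMA1 was at -1.54, at a list adjusted p = 0.217. Of 21 antenna genes, 0 were higher and 12 lower (0 and 13 adjusted over the list alone, 1 and 3 after rescaling, 6 to 11 lower with libraries left out). LHCA3 was at -1.24 and LHCA9 at -1.47, at a list adjusted p = 0.217.

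In limma 5980 of 14731 genes passed at 24 h, 848 higher and 5132 lower in tpt10b, and 4 of 32 lists passed, 3 after rescaling. Rescaling gave 5972 genes, of which 48.0% were higher in tpt10b against 14.2% in TPM as deposited. The filter at a mean of 5 TPM left 3448.

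At 48 h fewer genes differed than at 0 h or 24 h. ICL1 (Cre06.g282800), isocitrate lyase of the glyoxylate cycle, stood at 3361 ± 122 TPM in tpt10b and 1702 ± 349 in WT, a log2 difference of 1.00 ± 0.13 (adjusted p = 2.76e-04). BST1 (Cre16.g662600), a bestrophin-like channel of the carbon-concentrating mechanism, stood at 6.45 ± 0.340 and 15.4 ± 2.54 (-1.12 ± 0.12). PTB2 was again the largest rise among genes with symbols, 18.7 ± 1.62 TPM against 4.09 ± 1.27 (1.98 ± 0.23), and the truncated hemoglobin THB8 (Cre16.g661200) the largest fall among genes with symbols, 2.97 ± 0.221 against 10.6 ± 3.24 (-1.51 ± 0.19).

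Other large falls at 48 h were FAP1 (-1.51), LHCSR3B (-1.26), a stress-related antenna protein of photoprotection, FAP381 (-1.16) and HBP1 (-1.02). CPLD4 (-1.02), VSP4 (-0.92) and the early light-induced genes ELIP4 (-0.96, call lost after rescaling) and ELIP10 (-0.89) followed. Other large rises were ELIP9 (1.77), the mitochondrial genes cox1 (1.35) and cob (1.35), GGT1 (1.27) and the circadian clock gene ROC75 (1.26). HOPP1 (1.25), the pherophorin PHC52 (1.21), PFH3 (1.21) and GSL2 (1.18) followed.

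Numbers of list members at 48 h often depend on single libraries. Without WT 48 h replicate 2, 4 plastid ribosomal protein genes were lower, and 2 acetate and 2 starch breakdown genes were higher. Of 17 acetate and glyoxylate genes, 4 were higher and 0 lower (6 and 0 adjusted over the list alone, 3 and 0 after rescaling, 2 to 7 higher with libraries left out). PCK1 was at 0.63 and GFY1 at 0.71. The acetate list gave adjusted p = 5.80e-04, and adjusted p = 0.596 with an estimated correlation. Of 16 starch breakdown genes, 4 were higher and 0 lower (5 and 0 adjusted over the list alone, 4 and 0 after rescaling, 2 to 6 higher with libraries left out). They included the alpha-amylases AMA2 (1.05) and AMA3 (0.65, call lost after rescaling) and the glucan water dikinase GWD2 (0.83). The starch breakdown list gave adjusted p = 0.00286, and adjusted p = 0.706 with an estimated correlation. Of 51 cell cycle genes, 2 were higher and 0 lower (1 and 0 adjusted over the list alone, 2 and 0 after rescaling, 0 to 6 higher with libraries left out). MCM7 was at 0.73 and CYCD1 at 1.01. The cell cycle list gave adjusted p = 0.0304, and adjusted p = 0.852 with an estimated correlation, and adjusted p = 0.139 without WT 48 h replicate 2. Of 14 photoprotection genes, 0 were higher and 3 lower (0 and 3 adjusted over the list alone, 0 and 2 after rescaling, 0 to 4 lower with libraries left out). With ELIP4 these were OHP1 (-0.49) and LHCSR1 (-0.61). The photoprotection list gave adjusted p = 0.00501, and adjusted p = 0.497 with an estimated correlation. Of 18 carbon-concentrating genes, 1 was higher and 3 lower (3 and 3 adjusted over the list alone, 0 and 5 after rescaling, 0 to 4 higher with libraries left out). The pyrenoid linker EPYC1 was at -0.39 and LCI23 at -0.66, and the list ranked low. The carbon-concentrating list gave adjusted p = 0.00290, and adjusted p = 0.500 with an estimated correlation. Of 37 plastid ribosomal protein genes, 0 were higher and 11 lower (0 and 13 adjusted over the list alone, 0 and 10 after rescaling, 1 to 10 lower with libraries left out). PRPL22 was at -0.70, PRPL15 at -0.55 and PRPS20 at -0.47. The plastid ribosome list gave adjusted p = 2.57e-06, and adjusted p = 0.497 with an estimated correlation.

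Of 73 cytosolic ribosomal protein genes, 0 were higher and 1 lower (0 and 0 adjusted over the list alone, 0 and 0 after rescaling, 6 higher without WT 48 h replicate 1, 0 to 17 lower with libraries left out). RPL31 was at -0.35, and the list ranked low with a median of -0.17 (-0.21 to -0.10 with libraries left out). The cytosolic ribosome list gave adjusted p = 8.42e-10, and adjusted p = 0.495 with an estimated correlation. Of 29 chaperone genes, 0 were higher and 1 lower (0 and 1 adjusted over the list alone, 0 and 3 after rescaling, 0 to 2 lower with libraries left out). CPN20 was at -0.48. The chaperone list gave adjusted p = 0.0117, and adjusted p = 0.706 with an estimated correlation. Of 23 chlorophyll synthesis genes, 0 were higher and 1 lower (0 and 1 adjusted over the list alone, 0 and 3 after rescaling). UROD1 was at -0.79. The chlorophyll list gave adjusted p = 0.0327, and adjusted p = 0.852 with an estimated correlation. Of 10 photosystem I genes, 0 were higher and 0 lower (0 and 0 after rescaling), and the list ranked low. The photosystem I list gave adjusted p = 0.0241, and adjusted p = 0.500 with an estimated correlation. Of 15 fermentation genes, 5 were higher and 0 lower (6 and 1 adjusted over the list alone, 3 and 0 after rescaling, 3 higher without tpt10b 48 h replicate 3). PFR1 was at 1.12, ADH1 at 0.91 and the pyruvate formate lyase PFL1 at 0.86, but the list test gave an adjusted p = 0.147.

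At 48 h 971 of 14731 genes passed in limma, 766 higher and 205 lower, and 12 of 32 lists passed. Rescaling gave 845 genes with 57.0% higher, against 78.9% as deposited. This number rests on single libraries and settings: it was 2845 without WT 48 h replicate 1, 377 without WT 48 h replicate 2 and 249, 302 and 246 without tpt10b replicates 1, 2 and 3. It was 484 with a pseudocount of 0.1, 1571 with a pseudocount of 5, 136 with only the 6 libraries compared and 4227 with library weights. Of the 48 genes named for this time that passed, 45 passed after rescaling, 20 with only the 6 libraries compared, 37 and 42 without WT 48 h replicates 2 and 3, and 33, 35 and 36 without tpt10b replicates 1, 2 and 3.

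**Figure D3:**
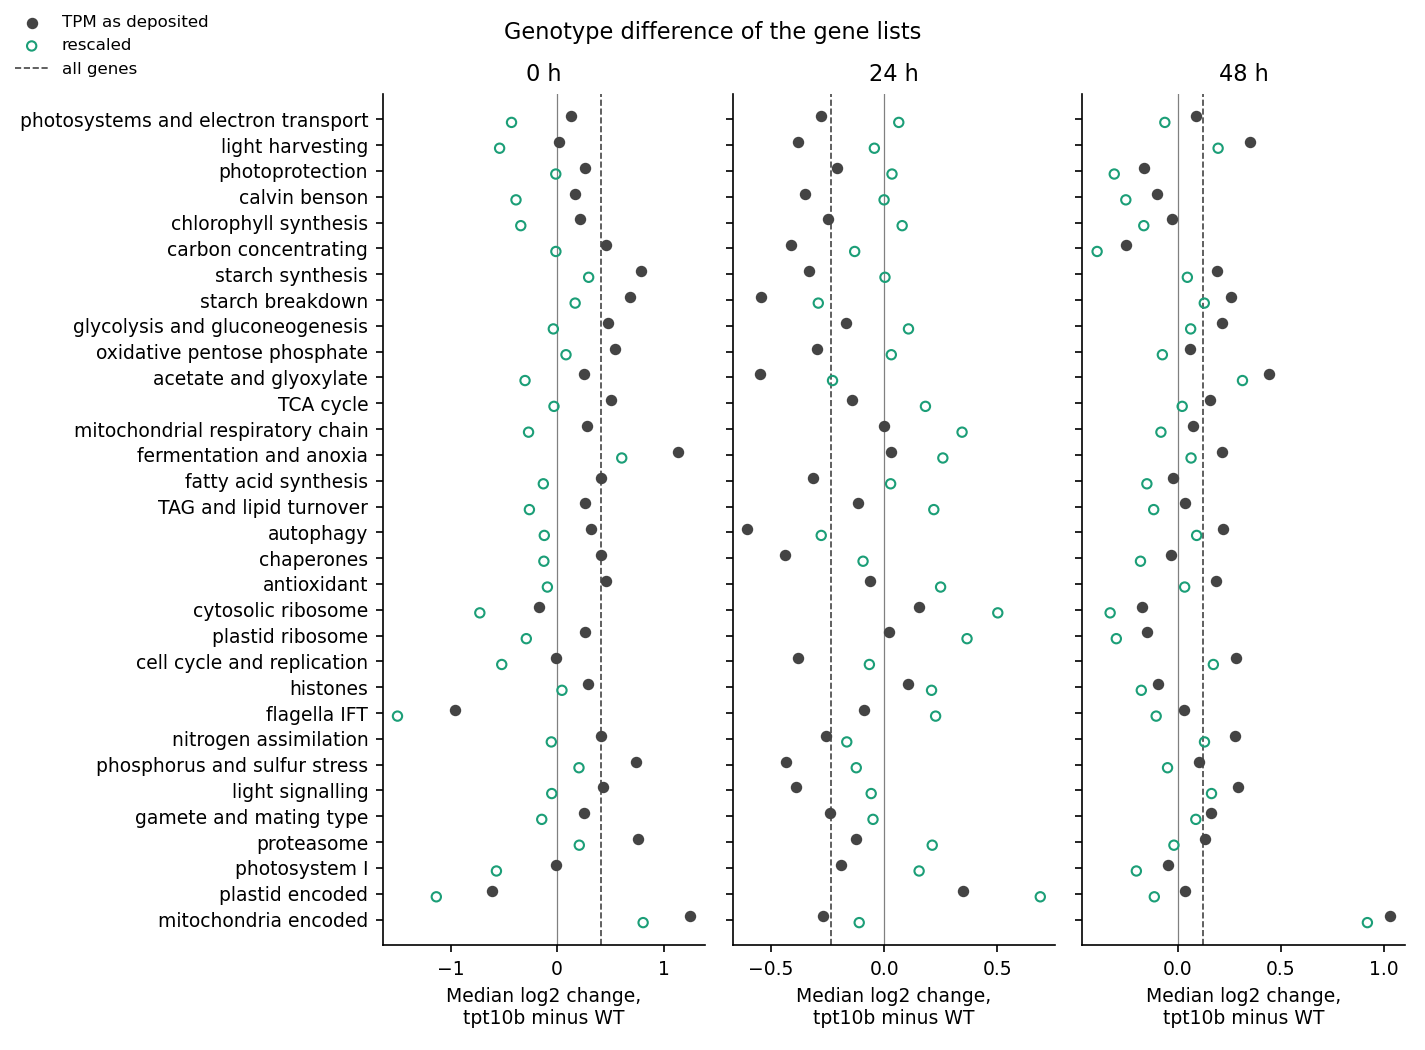
Median log2 difference of each gene list between tpt10b and WT at 0, 24 and 48 h, in TPM as deposited (filled) and after rescaling (open), with the median of all genes as a dashed line. The flagellar list at 0 h has a median of -0.96 as deposited and -1.50 after rescaling, and the antenna list at 0 h moves from 0.02 to -0.54, while the median of all genes moves from 0.41 to -0.02.

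Genes with a log2 difference of at least 1 at more than 1 time were few, though mostly more than expected for independent times. PTB2 was the only gene with a symbol higher in tpt10b by at least 1 in log2 at 0, 24 and 48 h, at 157 ± 6.94 TPM against 43.4 ± 8.02 at 0 h. FEA2 (-1.24, -1.90 and -1.41), singled out after its values were seen, and the targeted locus were lower at all 3 times to that extent. With a log2 size of at least 1, 15 genes were higher at both 0 and 24 h (5.15 expected by chance) and 27 lower (42.9 expected). At both 0 and 48 h, 27 were higher and 5 lower (6.56 and 0.814 expected), and at both 24 and 48 h, 12 were higher and 8 lower (0.610 and 2.61 expected). At any size 417 genes were higher at both 0 and 24 h, 364 at 0 and 48 h and 41 at 24 and 48 h (430.4, 388.8 and 44.1 expected). Lower at both were 358, 38 and 59 (471.7, 18.8 and 71.4 expected). Across genes, which are not independent replicates, the log2 differences at 24 and 48 h correlated at -0.477, and at -0.496 after rescaling. Those at 0 and 24 h correlated at -0.011 and those at 0 and 48 h at 0.084. Of the genes lower at 24 h, 369 were higher at 48 h where 266.9 were expected. WT 48 h replicate 2 deviated from the mean of its group along the genotype difference at 24 h, with a correlation of 0.630 across genes.

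In WT after 24 h of darkness, 18 of 21 antenna genes and 16 of 16 photosystem genes were lower than at 0 h and 25 of 29 chaperone genes higher. LHCA6 (Cre06.g278213), a photosystem I antenna gene, went from 1134 ± 40.5 to 27.5 ± 3.18 TPM (-5.32 ± 0.15, adjusted p = 2.22e-14). The photosystem II antenna gene LHCBM7 (Cre12.g548950) changed by -5.03 ± 0.21. The Rubisco large subunit gene rbcL went from 59.0 ± 15.6 to 1491 ± 423 TPM (4.62 ± 0.26), and the small heat shock gene HSP22B from 0.709 ± 0.243 to 35.0 ± 1.70 (4.41 ± 0.21). The comparison asks how WT transcripts respond to darkness with acetate. No samples kept in light for 24 h or 48 h were analysed, so darkness cannot be told apart from time in culture in any comparison with 0 h.

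The other largest falls in WT at 24 h were the pherophorins PHC18 (-6.80) and PHC5 (-5.99), FAP292 (-5.11), LIP1 (-4.97), FAP340 (-4.86), PSRP1 (-4.85), FAP170 (-4.84) and FAP222 (-4.80). The other largest rises included PHC66 (4.44), HSP22A (4.41), RRP6 (4.04), EFG12 (4.02), psaA_exon2 (3.99, also plastid), the cysteine dioxygenase CDO2 (3.95) and EZY3 (3.74). PFR1 rose as well (3.54), the hydrogenase HYDA1 fell (-2.04), and the lipid droplet protein gene MLDP1 rose (1.94).

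In this and the other dark comparisons, counts adjusted over the list alone were the same as those over all genes unless given. Of 16 photosystem and electron transport genes, 0 rose and 16 fell, PETO1 by -4.44 and PSBP1 by -3.43. The photosystem list gave adjusted p = 4.85e-12, and adjusted p = 0.0581 with an estimated correlation. Of 21 antenna genes, 2 rose and 18 fell. The antenna list gave adjusted p = 2.16e-12, and adjusted p = 0.181 with an estimated correlation. Of 23 chlorophyll synthesis genes, 0 rose and 20 fell, with CPX1, coproporphyrinogen oxidase, at -3.07. The chlorophyll list gave adjusted p = 1.00e-10, and adjusted p = 0.227 with an estimated correlation. Of 13 Calvin cycle genes, 1 rose and 8 fell (2 and 8 adjusted over the list alone), with the phosphoribulokinase PRK1 at -3.67. The Calvin cycle list gave adjusted p = 0.00555, and adjusted p = 0.334 with an estimated correlation. Of 37 plastid ribosomal protein genes, 0 rose and 37 fell, PRPL7 by -2.60. The plastid ribosome list gave adjusted p = 4.05e-19, and adjusted p = 0.0329 with an estimated correlation. Of 10 photosystem I genes, 0 rose and 10 fell, PSAG1 by -4.23. The photosystem I list gave adjusted p = 5.47e-10, and adjusted p = 0.0304 with an estimated correlation. Of 45 flagellar genes, 0 rose and 42 fell, RSP9 by -3.71 and IFT80 by -3.76. The flagellar list gave adjusted p = 3.43e-23, and adjusted p = 0.177 with an estimated correlation.

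Of 51 cell cycle genes, 10 rose and 29 fell (11 and 29 adjusted over the list alone), with the cyclin CYCB1 at -2.94. The cell cycle list gave adjusted p = 6.57e-04, and adjusted p = 0.761 with an estimated correlation. Of 17 acetate and glyoxylate genes, 1 rose and 11 fell (7 to 10 fell with libraries left out), with the malate synthase MAS1 at -1.24 and ACS1 at 1.23. The acetate list gave adjusted p = 0.0163, and adjusted p = 0.761 with an estimated correlation. Of 27 TCA cycle genes, 3 rose and 13 fell, with PDH2 at -2.37. The TCA cycle list gave adjusted p = 0.0191, and adjusted p = 0.761 with an estimated correlation. Of 17 fatty acid synthesis genes, 4 rose and 9 fell (4 and 10 adjusted over the list alone), with the biotin carboxyl carrier gene BCC2 at -3.04. The fatty acid list gave adjusted p = 0.0163, and adjusted p = 0.609 with an estimated correlation. Of 64 nuclear respiratory chain genes, 15 rose and 28 fell (15 and 29 adjusted over the list alone), with COX90 at -0.92. The respiratory chain list gave adjusted p = 0.0236, and adjusted p = 0.679 with an estimated correlation. Of 29 chaperone genes, 25 rose and 2 fell, among them BIP2 (2.67) of the endoplasmic reticulum. The chaperone list gave adjusted p = 1.17e-04, and adjusted p = 0.391 with an estimated correlation. Of 16 autophagy genes, 15 rose and 0 fell, with ATG12 at 2.25. The autophagy list gave adjusted p = 1.19e-04, and adjusted p = 0.386 with an estimated correlation.

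In limma 9776 genes changed in WT at 24 h, 5974 up and 3802 down, and 15 of 32 lists passed. After rescaling 48.4% of 9748 genes rose, against 61.1% as deposited, and the filter at a mean of 5 TPM left 5996 genes.

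By 48 h in WT 15 of 16 photosystem genes were low against 0 h. By then 12 of 15 nitrogen assimilation genes and 15 of the 18 histone genes kept by the filter had risen. PCY1 (Cre03.g182551), plastocyanin, went from 7703 ± 347 to 166 ± 48.1 TPM (-5.58 ± 0.18, adjusted p = 1.00e-13), and the flagellar membrane glycoprotein gene FMG1B (Cre09.g392867) changed by -5.33 ± 0.23. The pherophorin PHC66 (Cre02.g081700) rose by 8.02 ± 0.28, to 549 ± 123 TPM. AMT1A, an ammonium transporter, rose by 3.30 ± 0.19 to 9.07 ± 1.89 TPM.

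Further falls at 48 h were PHC18 (-6.71), PHC5 (-5.95), LIP1 (-5.84), FAP170 (-5.62), FAP340 (-5.49), LHCA5 (-5.37), LHCA6 (-5.14) and FAP215 (-5.12). Further rises were PHC30 (6.37), EZY3 (5.43), the glutathione S-transferase GSTS1 (5.34), the potassium transporter KUP2 (5.06), UBQ1 (4.99), AIH2 (4.78), CDO2 (4.74), PAO5 (4.47) and ELIP10 (4.46).

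Of 16 photosystem and electron transport genes, 0 rose and 15 fell, PETO1 by -4.78. The photosystem list gave adjusted p = 2.87e-09, and adjusted p = 0.131 with an estimated correlation. Of 21 antenna genes, 2 rose and 18 fell, LHCA1 by -4.28. The antenna list gave adjusted p = 8.50e-10, and adjusted p = 0.254 with an estimated correlation. Of 23 chlorophyll synthesis genes, 1 rose and 20 fell, with the cyclase gene CHL27A at -4.90. The chlorophyll list gave adjusted p = 3.63e-08, and adjusted p = 0.287 with an estimated correlation. Of 13 Calvin cycle genes, 1 rose and 8 fell, PRK1 by -4.16. The Calvin cycle list gave adjusted p = 0.00630, and adjusted p = 0.287 with an estimated correlation. Of 37 plastid ribosomal protein genes, 0 rose and 36 fell. The plastid ribosome list gave adjusted p = 3.88e-17, and adjusted p = 0.0456 with an estimated correlation. Of 10 photosystem I genes, 0 rose and 10 fell. The photosystem I list gave adjusted p = 7.58e-08, and adjusted p = 0.0456 with an estimated correlation. Of 64 nuclear respiratory chain genes, 8 rose and 48 fell, with CYC1 at -1.94. The respiratory chain list gave adjusted p = 2.02e-06, and adjusted p = 0.180 with an estimated correlation. Of 27 TCA cycle genes, 2 rose and 20 fell, with the succinate dehydrogenase subunit SDH4 at -1.88. The TCA cycle list gave adjusted p = 3.53e-05, and adjusted p = 0.339 with an estimated correlation. Of 17 acetate and glyoxylate genes, 1 rose and 13 fell, MAS1 by -2.59 and ICL1 by -1.31. The acetate list gave adjusted p = 9.75e-04, and adjusted p = 0.390 with an estimated correlation.

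Of 17 fatty acid synthesis genes, 4 rose and 12 fell, with BCC1 at -3.19. The fatty acid list gave adjusted p = 0.0243, and adjusted p = 0.456 with an estimated correlation. Of 51 cell cycle genes, 10 rose and 30 fell, with CYCB1 at -4.52. The cell cycle list gave adjusted p = 0.00540, and adjusted p = 0.801 with an estimated correlation. Of 45 flagellar genes, 1 rose and 43 fell (2 and 43 adjusted over the list alone), with the beta-tubulin TUB2 at -4.19. The flagellar list gave adjusted p = 2.25e-15, and adjusted p = 0.256 with an estimated correlation. Of 18 carbon-concentrating genes, 13 rose and 2 fell, LCI9 by 4.05 and BST1 by 3.23. The carbon-concentrating list gave adjusted p = 0.00406, and adjusted p = 0.339 with an estimated correlation. Of 15 nitrogen assimilation genes, 12 rose and 1 fell. The nitrogen list gave adjusted p = 0.00969, and adjusted p = 0.344 with an estimated correlation. Of 18 histone genes, 15 rose and 0 fell, HFO25 by 3.24. The histone list gave adjusted p = 0.00765, and adjusted p = 0.164 with an estimated correlation. Of 16 autophagy genes, 14 rose and 1 fell. The autophagy list gave adjusted p = 0.00116, and adjusted p = 0.344 with an estimated correlation. Of 14 photoprotection genes, 9 rose and 3 fell, with the violaxanthin de-epoxidase CVDE1 at 3.89 and ELIP3 at 3.96. The photoprotection list gave adjusted p = 0.0288, and adjusted p = 0.339 with an estimated correlation, and adjusted p = 0.0502 without WT 48 h replicate 2.

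At 48 h in WT 10337 genes changed in limma, 5559 up and 4778 down, and 17 of 32 lists passed. The filter at a mean of 5 TPM left 6457.

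In tpt10b after 24 h of darkness, PFH10 and FDX5 were below their high levels at 0 h, together with 16 of 16 photosystem genes. FDX5 went from 239 ± 35.0 to 1.13 ± 0.513 TPM (-6.83 ± 0.34, adjusted p = 2.19e-11) and PFH10 from 489 ± 39.96 to 3.75 ± 0.660 (-6.69 ± 0.17). LHCBM7 changed by -5.82 ± 0.21 and CHL27A by -5.48 ± 0.18. Plastid-encoded transcripts rose, rbcL by 6.05 ± 0.26 and ycf12 by 5.23, again with organelle RNA capture unknown. The comparison asks how the mutant responds to darkness, and its 24 h libraries stand apart as described.

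Further falls were PFH9 (-6.38), PSRP1 (-6.33), LHCA6 (-5.51), FAP340 (-5.49), LHCA9 (-5.44) and the phosphate transporter PTB3 (-5.31). Further rises included PHC66 (5.16), EZY3 (5.05), rps12 (4.50), the plastid loci CreCp.g802285 (4.65) and CreCp.g802321 (4.49), and psaA_exon3 (4.41).

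Lists of photosynthesis fell together in tpt10b at 24 h: photosystem and electron transport genes (0 rose and 16 fell of 16), antenna genes (2 and 19 of 21), chlorophyll synthesis genes (1 and 22 of 23), photosystem I genes (0 and 10 of 10) and plastid ribosomal protein genes (0 and 37 of 37). Their tests gave adjusted p from 2.63e-10 to 1.28e-05, and adjusted p from 0.139 to 0.474 with an estimated correlation. In carbon metabolism the falling lists were Calvin cycle genes (0 rose and 10 fell of 13, 3 and 10 after rescaling), fatty acid synthesis genes (0 and 15 of 17, 3 and 10 rescaled), acetate and glyoxylate genes (1 and 15 of 17, 2 and 10 rescaled), starch breakdown genes (1 and 15 of 16, 2 and 9 rescaled) and fermentation genes (1 and 11 of 15, 4 and 9 rescaled), with HYDA1 at -2.89. These gave adjusted p from 0.0103 to 0.0281, and adjusted p from 0.474 to 0.669 with an estimated correlation. Of 27 TCA cycle genes, 2 rose and 23 fell (5 and 13 after rescaling). The TCA cycle list gave adjusted p = 0.0189, and adjusted p = 0.657 with an estimated correlation, and adjusted p = 0.168 after rescaling. Of 20 proteasome genes, 0 rose and 18 fell (1 and 9 after rescaling). The proteasome list gave adjusted p = 0.0211, and adjusted p = 0.669 with an estimated correlation, and adjusted p = 0.168 after rescaling. Flagellar and cell cycle lists fell as well: flagellar genes (0 rose and 42 fell of 45, 2 and 39 after rescaling) and cell cycle genes (3 and 39 of 51, 11 and 29 rescaled). They gave adjusted p from 4.87e-08 to 0.0189, and adjusted p from 0.474 to 0.776 with an estimated correlation.

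Of 73 cytosolic ribosomal protein genes, 52 rose and 5 fell (68 and 0 after rescaling, 2 to 5 fell with libraries left out). The cytosolic ribosome list gave adjusted p = 1.37e-14, and adjusted p = 0.139 with an estimated correlation. Of 16 autophagy genes, 8 rose and 4 fell (9 and 4 adjusted over the list alone, 12 and 1 after rescaling, 2 fell without tpt10b 24 h replicate 3), and the list ranked high. The autophagy list gave adjusted p = 4.95e-04, and adjusted p = 0.474 with an estimated correlation. Of 29 chaperone genes, 7 rose and 7 fell (6 and 7 adjusted over the list alone, 20 and 2 after rescaling), with a median of 0.05 (-0.04 to 0.11 with libraries left out) where that of all genes was -0.53. The chaperone list gave adjusted p = 0.0123, and adjusted p = 0.622 with an estimated correlation.

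In tpt10b 11075 genes changed at 24 h in limma, 2667 up and 8408 down, and 18 of 32 lists passed. After rescaling 47.1% of 10650 genes rose, against 24.1% as deposited, and the filter at a mean of 5 TPM left 6670 genes.

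At 48 h tpt10b had low levels of PFH10 and plastocyanin and high levels of the pherophorins PHC66 and PHC30 against 0 h. PFH10 fell to 2.13 ± 0.481 TPM (-7.30 ± 0.17, adjusted p = 1.95e-15), and plastocyanin, PCY1, changed by -5.40 ± 0.18. PHC66 rose by 8.47 ± 0.28 and PHC30 by 7.54 ± 0.23. EZY3 rose by 6.67, CDO2 by 5.41, GSTS1 by 5.26, KUP2 by 5.07, AMX2 by 5.05, UBQ1 by 4.94, LCI9 by 4.93 and MMP11, a matrix metalloprotease, by 4.90. FAP340 (-5.98), CHL27A (-5.97), FAP215 (-5.92), PFH9 (-5.78), PHC5 (-5.55), PETO1 (-5.46), the thiazole synthase THI4 (-5.20) and PHC18 (-5.10) completed the largest falls.

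Lists of photosynthesis were low in tpt10b at 48 h against 0 h: photosystem and electron transport genes (1 rose and 15 fell of 16), antenna genes (3 and 18 of 21), chlorophyll synthesis genes (1 and 19 of 23), Calvin cycle genes (1 and 9 of 13), photosystem I genes (0 and 10 of 10) and plastid ribosomal protein genes (0 and 36 of 37). Their tests gave adjusted p from 7.66e-14 to 0.0162, and adjusted p from 0.0917 to 0.378 with an estimated correlation. Lists of respiration and carbon use fell too: nuclear respiratory chain genes (7 rose and 49 fell of 64), TCA cycle genes (1 and 25 of 27), acetate and glyoxylate genes (1 and 15 of 17), fatty acid synthesis genes (3 and 11 of 17, 4 and 11 adjusted over the list alone) and fermentation genes (3 and 12 of 15). Those tests gave adjusted p from 1.89e-05 to 0.0413, and adjusted p from 0.276 to 0.528 with an estimated correlation. Of 45 flagellar genes, 2 rose and 38 fell. The flagellar list gave adjusted p = 5.25e-06, and adjusted p = 0.496 with an estimated correlation. Of 20 proteasome genes, 1 rose and 14 fell (2 and 10 after rescaling). The proteasome list gave adjusted p = 0.0490, and adjusted p = 0.679 with an estimated correlation, and adjusted p = 0.119 after rescaling. Lists that ranked high were carbon-concentrating genes (11 rose and 4 fell of 18), nitrogen assimilation genes (9 and 1 of 15), histone genes (12 and 2 of 18), autophagy genes (12 and 2 of 16) and cytosolic ribosomal protein genes (32 and 1 of 73). The tests of these gave adjusted p from 4.10e-04 to 0.00993, and adjusted p from 0.246 to 0.378 with an estimated correlation.

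At 48 h in tpt10b 10937 genes changed in limma, 4438 up and 6499 down, and 19 of 32 lists passed. After rescaling 50.8% of the genes that changed had risen, against 40.6% as deposited, and the filter at a mean of 5 TPM left 6676.

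**Figure D4:**
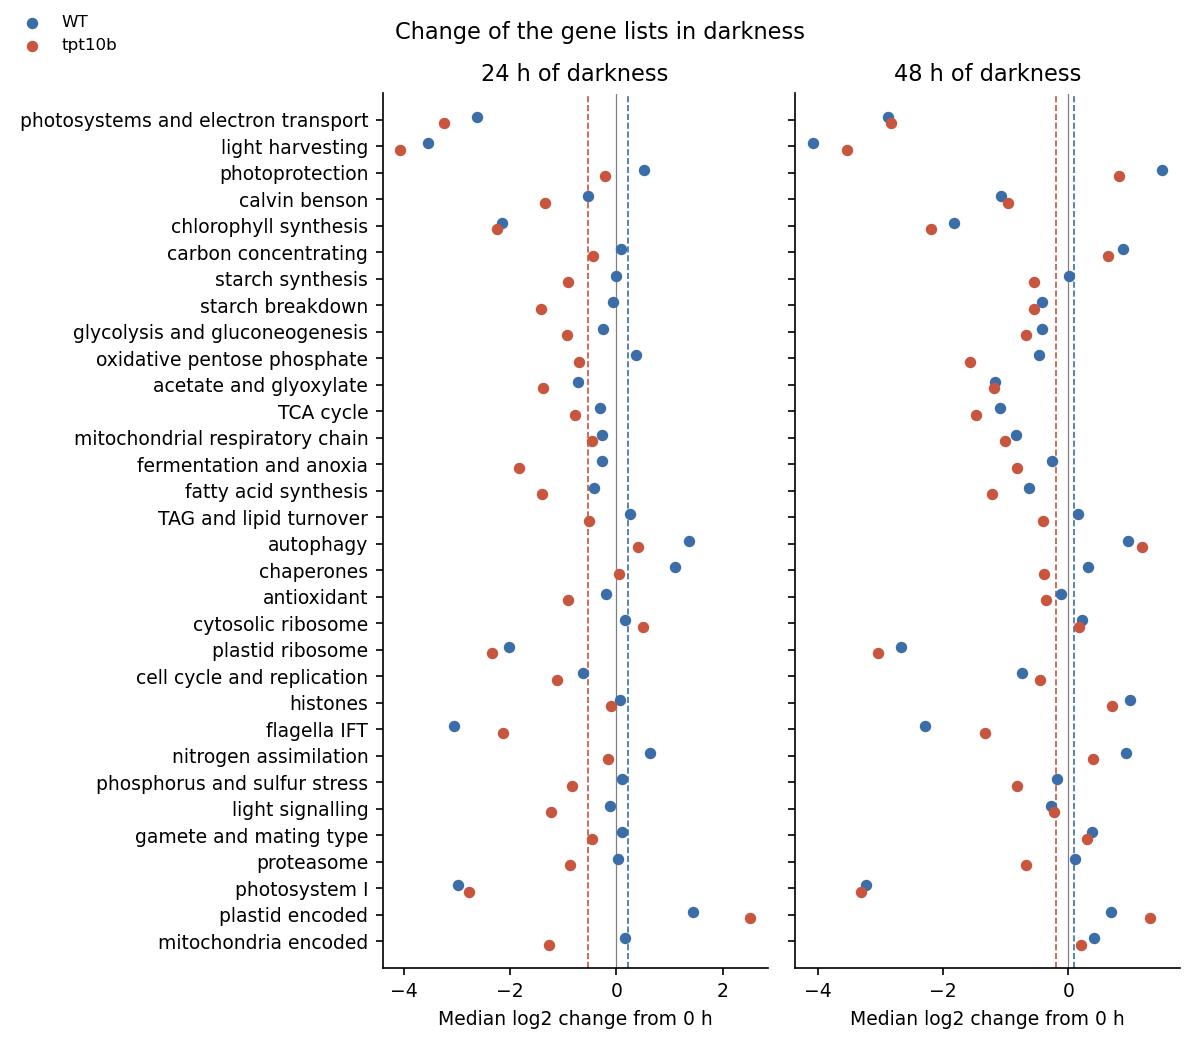
Median log2 change of each gene list after 24 h and 48 h of darkness against 0 h in WT (blue) and tpt10b (red), with the median of all genes of each contrast as a dashed line. The photosystem list has a median of -2.63 in WT and -3.25 in tpt10b at 24 h.

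Between 24 h and 48 h of darkness, more respiratory chain and chaperone genes fell than rose in both genotypes. In WT the falling lists were nuclear respiratory chain genes (2 rose and 51 fell of 64, 2 and 52 adjusted over the list alone), chaperone genes (1 and 22 of 29, 2 and 22 adjusted over the list alone), TCA cycle genes (2 and 17 of 27), acetate and glyoxylate genes (3 and 11 of 17, 3 and 12 adjusted over the list alone) and plastid ribosomal protein genes (0 and 28 of 37). Their tests gave adjusted p from 1.50e-08 to 0.00371, and adjusted p from 0.153 to 0.738 with an estimated correlation. Of 18 histone genes, 12 rose and 0 fell (14 and 0 adjusted over the list alone). The histone list gave adjusted p = 3.97e-07, and adjusted p = 0.0106 with an estimated correlation. The other rising lists in WT were carbon-concentrating genes (11 rose and 2 fell of 18), photoprotection genes (7 and 1 of 14, 7 and 2 adjusted over the list alone), flagellar genes (25 and 2 of 45, 27 and 2 adjusted over the list alone) and nitrogen assimilation genes (6 and 0 of 15, 6 and 1 adjusted over the list alone). These tests gave adjusted p from 2.20e-07 to 0.0288, and adjusted p from 0.169 to 0.669 with an estimated correlation. Each tpt10b value here rests on the 24 h libraries that stand apart. In tpt10b the falling lists were nuclear respiratory chain genes (13 rose and 36 fell of 64, 14 and 36 adjusted over the list alone), chaperone genes (3 and 16 of 29), TCA cycle genes (6 and 11 of 27) and plastid ribosomal protein genes (8 and 24 of 37, 4 to 6 rose with libraries left out). Their tests gave adjusted p from 2.04e-08 to 0.00258, and adjusted p from 0.354 to 0.790 with an estimated correlation. Of 73 cytosolic ribosomal protein genes, 13 rose and 33 fell (13 and 32 adjusted over the list alone, 4 and 49 after rescaling). The cytosolic ribosome list gave adjusted p = 6.44e-05, and adjusted p = 0.694 with an estimated correlation. Rising lists in tpt10b were carbon-concentrating genes (13 rose and 2 fell of 18, 12 and 3 after rescaling), nitrogen assimilation genes (11 and 1 of 15, 10 and 2 rescaled), flagellar genes (28 and 1 of 45, 20 and 5 rescaled) and cell cycle genes (30 and 1 of 51, 24 and 5 rescaled). Their tests gave adjusted p from 0.0168 to 0.0499, and adjusted p from 0.781 to 0.914 with an estimated correlation. The flagellar and cell cycle lists had adjusted p = 0.108 and 0.0542 after rescaling. Rescaling moved the median change of all genes from -0.10 to 0.02 in WT and from 0.29 to 0.05 in tpt10b. In limma 6115 genes changed in WT, 2472 up and 3643 down. There were 9820 in tpt10b, 6848 up and 2972 down. After rescaling 53.7% of the genes that changed rose in WT, against 40.4% as deposited, and 53.5% in tpt10b, against 69.7%.

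The change from 0 h differed between the genotypes, tested as the interaction of genotype and time. The 24 h interaction rests on the tpt10b 24 h libraries that stand apart. At 24 h the interaction was negative for fermentation genes, so that their change in tpt10b lay below that in WT, FDX5 by -3.72 ± 0.48 (adjusted p = 2.70e-05), PFR1 by -3.15 ± 0.30, HCP1 by -2.33 and ADH1 by -1.73. Flagellar genes went the other way, RSP9 by 1.52 ± 0.22, RSP1 by 1.60, IFT20 by 1.37 and the alpha-tubulin TUA1 by 1.24. The flagellar list held 26 higher and 0 lower of 45 (26 and 0 adjusted over the list alone, 43 and 0 after rescaling) in this interaction. The flagellar interaction list gave adjusted p = 1.89e-27, and adjusted p = 0.236 with an estimated correlation. Of 15 fermentation genes, 0 were higher and 13 lower (0 and 13 adjusted over the list alone, 1 and 6 after rescaling). The fermentation interaction list gave adjusted p = 0.0220, and adjusted p = 0.874 with an estimated correlation, and adjusted p = 0.0534 after rescaling. Of 18 starch synthesis genes, 0 were higher and 16 lower (0 and 16 adjusted over the list alone, 2 and 8 after rescaling). The starch synthesis list gave adjusted p = 0.0220, and adjusted p = 0.874 with an estimated correlation, and adjusted p = 0.200 after rescaling. Of 18 histone genes, 1 was higher and 2 lower (0 and 1 adjusted over the list alone, 2 and 0 after rescaling, 1 to 4 lower with libraries left out), and although their median was -0.20 (-0.25 to -0.03 with libraries left out) the test pointed up. The histone list gave adjusted p = 0.0229, and adjusted p = 0.250 with an estimated correlation, and adjusted p = 0.672 after rescaling.

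Both interactions subtract the same 0 h libraries, so a difference at 0 h alone gives both the same sign, and their likeness is no separate evidence. At 48 h the interaction was positive for flagellar genes and negative for fermentation genes, HCP1 at -2.59 ± 0.25 and PFR1 at -2.09. Of 45 flagellar genes, 37 were higher and 0 lower (39 and 0 adjusted over the list alone, 42 and 0 after rescaling). The flagellar interaction list gave adjusted p = 1.50e-22, and adjusted p = 0.756 with an estimated correlation. Of 15 fermentation genes, 0 were higher and 9 lower (0 and 10 adjusted over the list alone, 0 and 6 after rescaling). The fermentation interaction list gave adjusted p = 0.00296, and adjusted p = 0.946 with an estimated correlation. Of 18 starch synthesis genes, 0 were higher and 9 lower (0 and 11 adjusted over the list alone, 1 and 1 after rescaling, 5 to 14 lower with libraries left out). The starch synthesis list gave adjusted p = 0.0467, and adjusted p = 0.946 with an estimated correlation, and adjusted p = 0.12 after rescaling.

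The interaction passed limma in 9456 genes at 24 h, 921 higher and 8535 lower in tpt10b relative to WT, and in 5212 at 48 h, 1328 higher and 3884 lower. Rescaling moved the median interaction of all genes from -0.65 to 0.05 at 24 h and from -0.27 to 0.05 at 48 h. It gave 6548 genes with 55.6% higher at 24 h, against 9.74% as deposited, and 3803 with 66.1% higher at 48 h, against 25.5%. The filter at a mean of 5 TPM left 5471 and 3333, quantile normalisation 6159 at 24 h, and limma-voom and library weights 3296 and 9579 at 48 h.

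**Figure D5:**
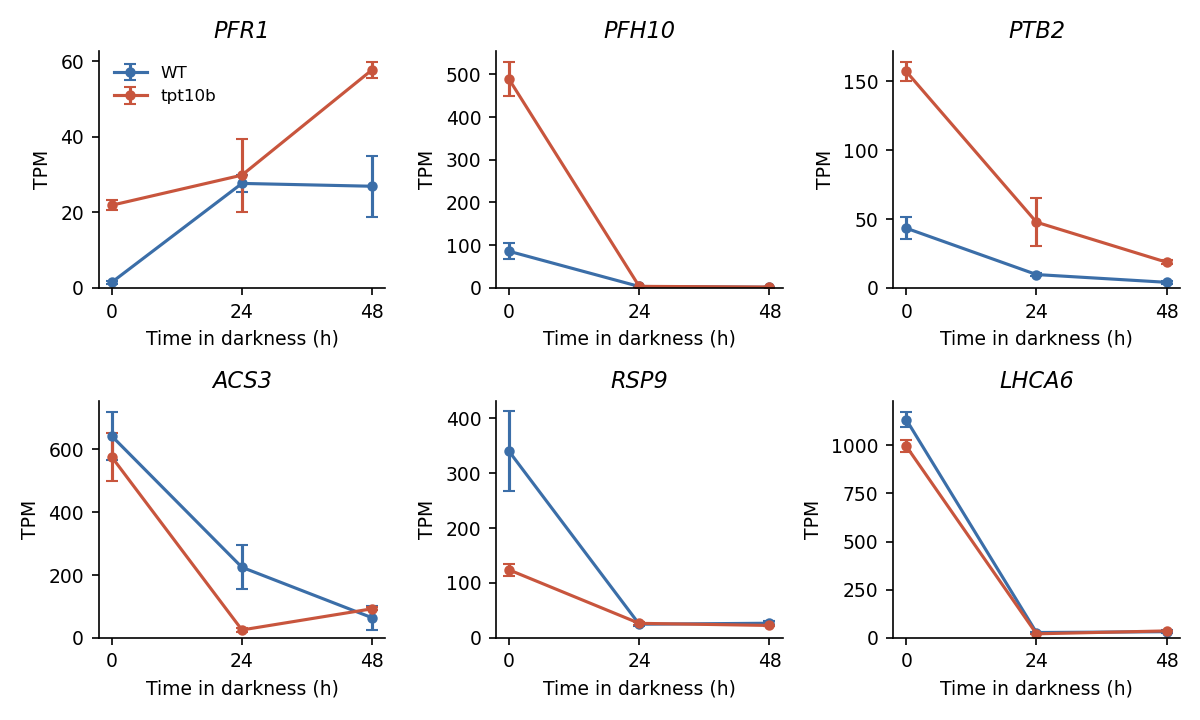
Mean TPM with SD, n = 3 libraries, of PFR1, PFH10, PTB2, ACS3, RSP9 and LHCA6 at 0, 24 and 48 h in WT and tpt10b. PFR1 stands at 21.9 ± 1.35 TPM in tpt10b and 1.49 ± 0.386 in WT at 0 h.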

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

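All tests of explanations in this part were chosen after the results they address had been seen, while the interaction tests were planned.

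Genes whose change from 0 h differed between tpt10b and WT drew attention because the interaction itself was tested, with the same 0 h libraries at both times: 9456 genes at 24 h and 5212 at 48 h. The largest negative interactions at 24 h among genes with symbols were FDX5 (-3.72), PRR1 (-3.41), NDA3 (-3.19), PFR1 (-3.15) and SNRK2H (-3.13). The largest positive ones were the plastid loci CreCp.g802284 (3.93) and CreCp.g802322 (3.92), petL (3.13), NRX3 (2.63) and FAP126 (2.48). Those plastid loci had near-equal values here and at 48 h and may not be separate signals. At 48 h they were HCP1 (-2.59), THB8 (-2.57), PFH10 (-2.23), AOF1 (-2.18) and FAP338 (-2.12) on the negative side. On the positive side stood CreCp.g802322 (2.88), CreCp.g802284 (2.85), chlL (2.75), VAMP4 (2.67) and RBCX2A (2.49).

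Lists that passed the interaction test in the same direction in both scalings were also singled out. At 24 h these were cytosolic ribosomal proteins, 23 higher and 3 lower of 73 (21 and 2 adjusted over the list alone, 68 and 1 after rescaling, 5 lower without tpt10b 24 h replicate 1) (adjusted p = 3.06e-20, and adjusted p = 0.0555 with an estimated correlation), flagellar genes (adjusted p = 1.89e-27, and adjusted p = 0.236 with an estimated correlation) and plastid-encoded genes, 37 higher and 0 lower of 74 (64 and 0 after rescaling) (adjusted p = 4.78e-33, and adjusted p = 0.544 with an estimated correlation). At 48 h antenna genes, 4 higher and 0 lower of 21 (1 and 0 adjusted over the list alone, 13 and 0 after rescaling, 1 to 8 higher with libraries left out) (adjusted p = 0.00296, and adjusted p = 0.946 with an estimated correlation), cell cycle genes, 10 higher and 5 lower of 51 (9 and 4 adjusted over the list alone, 24 and 3 after rescaling, 5 to 18 higher with libraries left out, 8 lower without WT 48 h replicate 2) (adjusted p = 3.04e-04, and adjusted p = 0.946 with an estimated correlation), flagellar genes (adjusted p = 1.50e-22, and adjusted p = 0.756 with an estimated correlation) and plastid-encoded genes, 14 higher and 0 lower of 74 (28 and 0 after rescaling, 5 to 31 higher with libraries left out) (adjusted p = 1.34e-12, and adjusted p = 0.946 with an estimated correlation), ranked high. Cytosolic ribosomal proteins, 1 higher and 0 lower of 73 (0 and 0 adjusted over the list alone, 15 and 0 after rescaling, 0 to 3 higher with libraries left out), ranked high with a median of 0.00 (-0.02 to 0.06 with libraries left out) and a mean of 0.01 (adjusted p = 0.0163, and adjusted p = 0.946 with an estimated correlation). Fermentation genes (adjusted p = 0.00296, and adjusted p = 0.946 with an estimated correlation), chaperones, 0 higher and 12 lower of 29 (0 and 15 adjusted over the list alone, 0 and 4 after rescaling, 19 lower without WT 48 h replicate 2) (adjusted p = 0.0223, and adjusted p = 0.946 with an estimated correlation), and proteasome genes, 0 higher and 11 lower of 20 (0 and 5 after rescaling) (adjusted p = 0.0101, and adjusted p = 0.946 with an estimated correlation), ranked low.

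The split of differing genes was uneven between the genotypes, 84.7% higher in tpt10b at 0 h and 14.2% at 24 h. Recomputing TPM without ribosomal protein and organelle genes left 79.5% and 29.4% higher, which argues against those transcripts as the whole cause. Removing a trend on coding length left 13.9% higher at 24 h, with 5581 of the 5980 genes called again in the same direction. Most single calls thus did not rest on a length trend. Each library kept its mean in that step, so a shift common to all genes could not move, and the uneven split is not decided by it. Rescaling gave 38.5% and 48.0%, but it centres the changes by construction, so a shift in most transcripts and the scaling to a fixed total cannot be told apart without a measure of RNA per cell. A general change in the mutant's transcripts, which the design names, stays open and untested.

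Genes with reads were fewer in tpt10b at 24 h, with a difference of -872 on average. After thinning to the smallest library the difference was -879.5, with each tpt10b library still below each WT library, which argues against depth. The deviation of WT 48 h replicate 2 from its group correlated at 0.630 across genes with the 24 h genotype difference. Replicates 1 and 3 gave -0.636 and -0.343, and deviations within a group are not independent. A state of single cultures or RNA preparations may therefore contribute, and it cannot be told apart from the genotype because all 3 tpt10b 24 h libraries share it.

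Flagellar transcripts were lower in tpt10b at 0 h, with a median of -0.957 over 45 members. Leaving out each 0 h library in turn kept the median between -1.11 and -0.801, which argues against a single library. Of 10000 random lists matched on coding length and mean level, 0 had a median as low, and 95% of them lay between 0.271 and 0.556. The scaling moves all genes of a library by a common factor, so this distance from lists of the same level argues against the scaling, while rescaling could only lower the median further and decides nothing. Random lists leave out the correlation between flagellar genes, and the list test lost its call with an estimated correlation (adjusted p = 0.133). A lower level of these transcripts in the mutant is a candidate explanation, found and tested on the same data, and a difference between cultures in stage or handling was not tested.

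Other splits of the same libraries were counted for each number of genes. For the 9 comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and 1 of 10, the real split, gave as many genes in each. The real and highest other numbers were 8831 and 1 at 0 h, 5980 and 1 at 24 h, and 971 and 44 at 48 h for tpt10b against WT. In WT they were 9776 and 0 at 24 h, 10337 and 0 at 48 h, and 6115 and 499 for 48 h against 24 h, and in tpt10b 11075 and 0, 10937 and 0, and 9820 and 0. For the interaction at 24 h, 1 of 100 splits, the real one, gave as many genes as the real 9456. The 10 that kept the 0 h libraries of each genotype together gave 3101 to 5980 genes. The 10 that kept the 24 h libraries together gave 416 to 2916, and the 79 that mixed the genotypes at both times gave 0. These numbers follow the genotype difference at single times, so the splits do not decide on the interaction itself. For the interaction at 48 h, 6 of 100 gave as many as the real 5212, the highest other being 7310, and a random grouping is not excluded by this count. The other 5 all kept the 0 h libraries of each genotype together and so carry the genotype difference at 0 h, and among the 79 splits that mixed the genotypes at both times the highest was 32.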

How the results depend on the processing

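Tests with limma-voom, TPM without ribosomal protein and organelle genes, library weights, corrected list matching, lists without WT 48 h replicate 2 and list members with each library left out were chosen after the results had been seen, and the other alternatives were planned. In tpt10b against WT the targeted locus kept its direction and call in all 54 values from alternatives. With each replicate left out its log2 difference stayed from -2.87 to -2.73 at 0 h, -4.07 to -3.67 at 24 h and -3.33 to -2.92 at 48 h. Of 216 numbers of genes from alternatives, 185 lay within 1.5 times the reported one. Of 5285 values for named genes, 5155 kept direction and side of the threshold, 128 lost and 2 gained a call, and of 1184 list values 1019 kept both, 141 lost and 23 gained a call and 1 reversed. With an estimated correlation 5 of 131 list calls held: plastid ribosome and photosystem I in WT at 24 h and 48 h, and histones in WT at 48 h against 24 h. The nuclear respiratory chain list at 0 h turned from up (adjusted p = 0.707) to down after rescaling (adjusted p = 0.00164, range over its alternatives 0.00164 to 0.882), and the cause was not tested. Without WT 48 h replicate 2, 11 of 12 list calls held for tpt10b against WT at 48 h, 16 of 17 for WT at 48 h against 0 h, 11 of 11 against 24 h and 9 of 9 for the interaction at 48 h. Of 3960 numbers of list members with a library left out, 3384 lay within 1.5 times the reported one. In simulated data 1.5-fold changes were recovered in 37.9% of genes, 33.3% up to and 42.4% above their median level, and what depth limits was not tested further.

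The filter at a mean of 5 TPM tests fewer genes and so gave fewer: 5297, 3448 (tpt10b against WT at 0 and 24 h), 5996, 6457, 4044 (WT at 24 h, 48 h and between), 6670, 6676, 5991 (tpt10b likewise), 5471 and 3333 (interactions). For the other alternatives that moved a number of genes beyond 1.5 times the cause was not tested. For tpt10b against WT at 0 h these were rescaling (5057), quantile normalisation (5456) and limma-voom (5139). At 48 h they were pseudocounts of 0.1 (484) and 5 (1571), the fit on compared groups only (136) and library weights (4227), and the replicate block gave 649. Interactions moved to 6159 with quantile normalisation at 24 h and to 3296 with limma-voom and 9579 with library weights at 48 h. With a log2 size of at least 1, genes shared between times were fewer by construction, 15 higher and 27 lower (0 and 24 h), 27 and 5 (0 and 48 h), and 12 and 8 (24 and 48 h). With each replicate left out the numbers ran from 7100 to 9004, 4183 to 6339 and 246 to 2845 for tpt10b against WT at 0, 24 and 48 h. They ran from 8975 to 9675, 9741 to 10604 and 4859 to 6022 in WT, 10422 to 10894, 10260 to 10392 and 9008 to 9852 in tpt10b, and 8493 to 9799 and 3836 to 6565 for the interactions.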

Other observations

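The test of genes higher at every time was chosen after the result had been seen. Organelle-encoded transcripts were grouped in lists added after the symbols were read. Since a poly(A) selection is not stated, their level and their capture by the libraries cannot be told apart. At 0 h the plastid-encoded genes had 0 higher and 26 lower of 74 (0 and 62 after rescaling, 17 lower without WT 0 h replicate 2) in tpt10b, psbF of photosystem II at -1.68 (adjusted p = 3.09e-23, and adjusted p = 0.787 with an estimated correlation), and plastid genes held 1.08% of TPM in tpt10b and 2.11% in WT. The mitochondria-encoded genes had 7 higher and 0 lower of 7 (6 and 0 after rescaling), with nad6 at 1.69 and the cytochrome oxidase subunit cox1 at 1.55, but their list test gave an adjusted p = 0.0607. At 24 h they had 0 higher and 0 lower of 7 (0 and 0 after rescaling), and the interaction at 24 h was negative in 7 of 7 (5 of 7 after rescaling), with a list adjusted p = 0.214. At 24 h plastid-encoded genes were on the high side in tpt10b, 17 higher and 0 lower of 74 (32 and 0 after rescaling, 8 to 24 higher with libraries left out) (adjusted p = 3.89e-10, and adjusted p = 0.975 with an estimated correlation). At 48 h they had 0 higher and 0 lower of 74 (0 and 0 after rescaling, 4 higher without WT 48 h replicate 1), a median of 0.04 (-0.28 to 0.31 with libraries left out) and a test that pointed down (adjusted p = 0.0327, and adjusted p = 0.852 with an estimated correlation), with adjusted p = 0.0984 after rescaling and adjusted p = 5.60e-08 without WT 48 h replicate 2 (range over its alternatives 5.60e-08 to 0.852). Mitochondria-encoded genes were higher in tpt10b at 48 h, 6 higher and 0 lower of 7 (5 and 0 after rescaling, 1 to 7 higher with libraries left out), with cob at 1.35 ± 0.23 and nad4 at 1.03 (adjusted p = 6.05e-05, and adjusted p = 0.500 with an estimated correlation).

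In darkness 52 rose and 4 fell of 74 of the plastid-encoded genes in WT at 24 h (adjusted p = 2.91e-05, and adjusted p = 0.761 with an estimated correlation). At 48 h against 0 h in WT 37 rose and 13 fell of 74 (5 to 19 fell with libraries left out), at a list adjusted p = 0.109, which was 0.0164 without WT 48 h replicate 2 (range over its alternatives 0.0164 to 0.958). In tpt10b 68 rose and 1 fell of 74 at 24 h (adjusted p = 3.28e-32, and adjusted p = 0.455 with an estimated correlation) and 51 rose and 0 fell of 74 at 48 h (adjusted p = 7.74e-08, and adjusted p = 0.573 with an estimated correlation). Between 24 h and 48 h 0 rose and 45 fell of 74 in WT (adjusted p = 2.65e-07, and adjusted p = 0.784 with an estimated correlation) and 2 rose and 52 fell of 74 in tpt10b (adjusted p = 1.57e-15, and adjusted p = 0.790 with an estimated correlation), where the mitochondria-encoded genes rose, 7 rose and 0 fell of 7 (adjusted p = 0.0273, and adjusted p = 0.791 with an estimated correlation). The stress-related antenna genes LHCSR3A and LHCSR3B rose in WT by 1.79 and 3.30 at 48 h and were -0.97 and -1.26 in tpt10b against WT. The sex-linked regulator MID1 fell in WT at 24 h (-2.71), and the translocators TPT2 and TPT3 fell in tpt10b at 24 h (-2.54 and -1.09).

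Genes higher in tpt10b at all 3 times by at least 1 in log2 numbered 11 (10 after rescaling), with 0.037 expected for independent times. Some of these, such as Cre15.g801845 (3.86, 2.35 and 1.65), were nearly absent in WT (0.0677 to 0.0987 TPM), so independent times cannot be assumed. Others of the 11 genes, such as PTB2 and Cre17.g802033 (3.28, 2.66 and 1.87), were expressed in WT. A genotype difference independent of light is a candidate explanation, and a strain sequence difference apart from the knockout was not tested. Genes lower at all 3 times numbered 3, where 0.079 were expected: the targeted locus, FEA2 and Cre16.g801947 (-1.29, -1.89 and -1.69).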
